A study of Mus musculus with 25 samples.

How the data were processed

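Total RNA from frozen mouse liver was amplified with the WT-Ovation Pico system, labelled with biotin and hybridized to 1-colour Affymetrix mouse gene arrays, per the labels' protocols. The strain is given as FVB;129. DEN was injected intraperitoneally at 20 mg/kg at 14 days of age, per the labels' treatment protocol, and the 24 h until collection are from the series text. The deposited values are log2 signals from RMA, which corrects the background, brings the probe distributions of the arrays to a common shape by quantile normalization and summarises each probe set by median polish. Per the submitters' processing notes it was run in Affymetrix Expression Console 1.1, with no version of RMA given. Whether all 25 arrays were normalized in 1 run is not stated, nor are the genome build and the sexes of the animals.

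The deposited table held 35555 probe sets on 25 arrays, and every column was used. Of these probe sets, 23409 were listed in the probe table supplied with the data, 21789 of them with 1 gene symbol and 1620 with several. The 12146 unlisted probe sets and those with several symbols were left out. Where a gene had several probe sets, that with the highest mean over all arrays was kept, which left 19938 genes. Of these, 3987 with a mean under the 20th percentile of the named probe sets (3.33 log2) were left out as dim, and 15951 were tested. A RefSeq gene table served for current symbols and for which genes lie on the same chromosome or next to each other.

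Groups were taken from the labels. The array names place the arrays in 3 sets, of 16, 4 and 5 arrays. Group means and a fixed term for the set were fitted to all 25 arrays with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, so that all groups share the residual spread. The 11 comparisons were DEN against untreated in WT and in DKO, the difference between these responses, DKO against WT untreated, the 6 pairs of the 4 DEN genotypes, and DKO minus p53KO minus RbKO plus WT after DEN. All tests were two-sided. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the genes tested in that comparison. SE is the moderated standard error of limma. Only set 1 holds all groups, and the fits within a set used the arrays of that set alone.

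A total of 26 gene lists was tested in each comparison with camera of limma at a preset inter-gene correlation of 0.01, adjusted over the lists of the comparison. Camera compares a list with all other genes. It was repeated with a correlation estimated from the residuals, and with fry, which asks whether the genes of a list move on balance in 1 direction. The lists were p53 targets, E2F and DNA replication genes, mitotic genes, replication-dependent histones, DNA repair, xenobiotic metabolism, Nrf2 targets, ER stress and ATF4, apoptosis, acute phase, inflammatory cytokines and chemokines, interferon-stimulated genes, cholesterol synthesis, lipogenesis, PPARalpha and ketogenesis, gluconeogenesis and amino acid catabolism, plasma protein and bile acid genes of hepatocytes, fetal liver genes, circadian genes, and markers of macrophages, neutrophils and myeloid precursors, lymphocytes, erythroid cells, endothelium, stellate cells and matrix, and cholangiocytes and progenitors. Members of a list were also adjusted over the list alone. The groups, the comparisons, the set term, the lists, the filters, the alternatives other than the 2 named as later additions and the rule for named genes were fixed before the data were examined. That rule takes, in each comparison, Rb1, the 6 largest rises and the 6 largest falls among called genes with the same sign within set 1, and up to 4 members of each described list in order of p. Which lists the text describes was chosen from their test results.

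The overlaps between genotype effects were set beside the product of the counts over the number of genes, beside 20 simulations without any effect in which whole residual vectors of arrays were redrawn for all 4 DEN groups, and beside 20 fits in which the DEN WT arrays were split into 3 and 2.

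The alternatives were no set term, the set as a random block (duplicateCorrelation, with statmod 1.5.0), each set alone, no filter, a filter at the 40th percentile, the mean of all probe sets of a gene, all probe sets with 1 symbol without choosing between them, each array centred on its median, another quantile normalization, array weights, eBayes with trend and robust settings, only the groups of the comparison in the fit, and each array of the groups compared left out in turn. The later additions, chosen after seeing the data, were a fit without set 2 and a fit with the log2 value of Xist as a covariate, since the labels do not give the sexes. Other splits of the arrays were fitted in the same way, all of them where there were up to 100 and otherwise 100 drawn with a fixed seed. Splits within the array sets were added after seeing the data.

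The calculation was tested on simulated data with the group sizes and the residual spread of the arrays and known changes put in. For DEN in WT it called 53.7% of genes changed 1.5-fold, 98.5% of those changed 2-fold and 100% of those changed 4-fold. For DKO against WT after DEN these were 47.8%, 97% and 100%, and for untreated DKO 35.8%, 80.6% and 100%. Among 15717, 15719 and 15717 unchanged genes, 12, 9 and 8 were called. The list that was shifted came first, with camera adjusted p of 1.48e-37, 6.08e-30 and 2.81e-35, and 0 other lists were called. The simulated genes were drawn independently, so this does not show how often the list test passes by chance in genes that vary together. Arrays have no read depth, so their number and their signal over background limit the precision.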

Results

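Expression was measured on 25 arrays of frozen mouse liver, each giving log2 values for 35555 probe sets. The mice carried Cre recombinase driven by the albumin promoter, which is active in hepatocytes, and loxP sites in Rb1 (the gene of the retinoblastoma protein, which restrains entry into S phase), in Trp53 (the gene of p53), in both, or in neither. These genotypes are called RbKO, p53KO, DKO and WT. Diethylnitrosamine (DEN), a liver carcinogen that hepatocytes convert into a DNA-alkylating agent, was injected at 20 mg/kg at 14 days of age, and livers were taken after 24 h. There were 3 untreated WT, 3 untreated DKO, 5 DEN WT, 5 DEN p53KO, 4 DEN RbKO and 5 DEN DKO arrays. The labels give the treatment of the untreated animals as none, whereas the series text speaks of saline. The labels do not say that replicates came from separate animals, so the p-values measure the spread between these samples. Their number limits the precision of every value below.

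The array names place the arrays in 3 sets. Set 1 holds 16 arrays of all 6 groups. Set 2 holds 4 arrays (1 untreated WT, 2 DEN WT, 1 DEN RbKO), and set 3 holds 5 (3 DEN p53KO, 2 DEN DKO). The first principal component carried 25.8% of the variance and had a mean of -11.9 in set 1, 46.6 in set 2 and 0.641 in set 3, so set 2 stood apart. Every comparison was therefore fitted with the set as a term. Values within set 1 are given beside the pooled ones for most described lists and for some of the named genes. Only DEN against untreated in WT and RbKO against WT could also be taken within set 2, and only DKO against p53KO within set 3.

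Rb1 itself was examined first (probe set 10421526). Its log2 signal was 5.34, 5.30 and 5.76 in untreated WT and 5.02, 5.02 and 4.76 in untreated DKO. After DEN it was 6.02, 5.90, 5.82, 5.97 and 5.04 in WT, 5.56, 5.76, 5.93, 5.91 and 5.68 in p53KO, 5.55, 5.64, 5.79 and 6.28 in RbKO, and 5.18, 5.57, 5.51, 5.82 and 5.35 in DKO. By limma, Rb1 was called in 0 of 11 comparisons, with an unadjusted p under 0.05 in 2. The difference from WT was -0.50 (SE 0.22, adjusted p = 0.336) in untreated DKO, -0.29 (SE 0.19, adjusted p = 0.355) in DEN DKO and 0.08 (SE 0.18, adjusted p = 0.830) in DEN RbKO. Without DEN WT replicate 5 the difference of DEN DKO was -0.42 (adjusted p = 0.0447) and DEN against untreated WT was 0.49 (adjusted p = 0.0445). Within set 1, Rb1 was called in 3 comparisons, DKO against WT after DEN at -0.49 (adjusted p = 0.0136), DEN in WT at 0.59 (adjusted p = 0.00807) and DEN in DKO at 0.49 (adjusted p = 0.00629). The probe set averages probes along the transcript, a loxP allele removes only part of it, and other liver cells keep the gene, so this signal checks the genotypes only weakly. Trp53 was not analysed here.

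**Figure D1:**
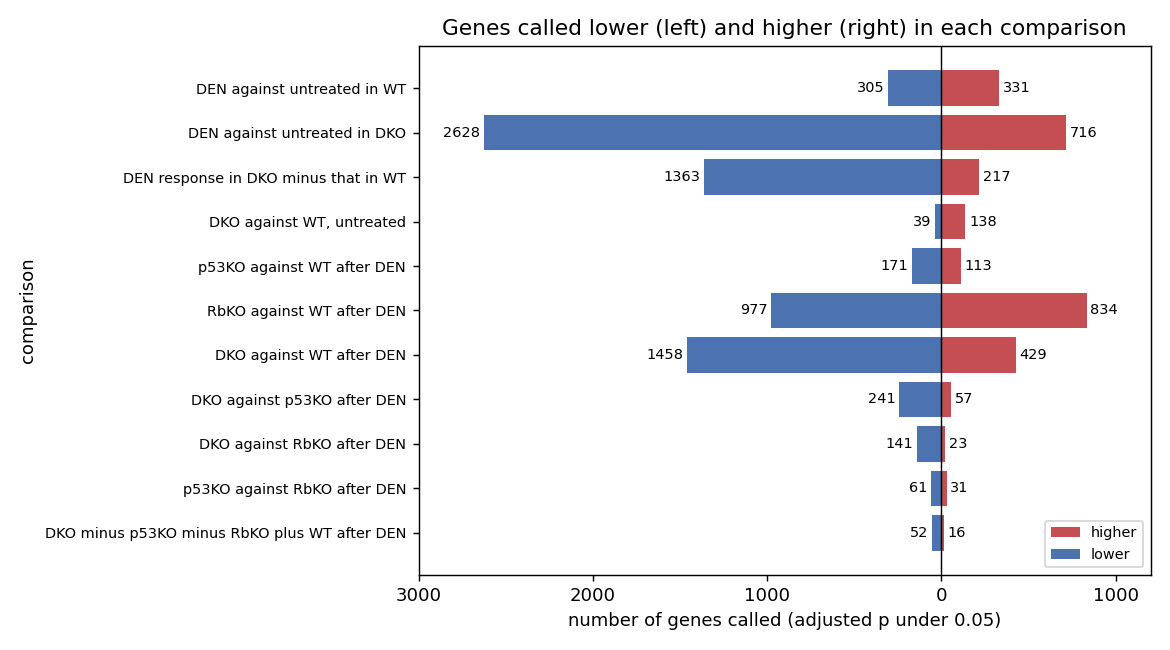
Number of genes (horizontal axis) called lower and higher at a limma adjusted p under 0.05 in each of the 11 comparisons, out of 15951 genes tested. The bars run from 68 genes for the non-additive part of the DKO effect to 3344 for DEN in DKO, of which 2628 were lower.

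What the carcinogen does to a WT liver within a day was asked by comparing 5 DEN with 3 untreated WT arrays. The serum amyloid genes Saa2 and Saa1 rose by 4.31 (SE 0.57) and 3.52 (SE 0.64) log2, and Hamp, which encodes the iron hormone hepcidin, rose by 3.98 (SE 0.68). Cplane1, 1700007K13Rik and Ddias rose by 3.16 (SE 0.36), 3.05 (SE 0.29) and 2.56 (SE 0.31). The largest falls were those of Naaladl2 at -2.17 (SE 0.44), Atp6v0d2 at -2.12 (SE 0.26) and Slc1a2 at -2.03 (SE 0.33), followed by Gdap10, the leptin receptor gene Lepr and Diaph2 at -1.79 (SE 0.40), -1.70 (SE 0.37) and -1.66 (SE 0.18). In all, 636 of 15951 genes were called, 331 higher and 305 lower, all with the same sign within set 1. The call of Naaladl2 ended without untreated WT replicate 1 (adjusted p = 0.0576). For Gdap10 and Lepr each of 2 arrays ended it, with adjusted p up to 0.0599 without untreated WT replicate 1 and 0.0736 without untreated WT replicate 2. The count was 221 without untreated WT replicate 1 and 266 without untreated WT replicate 2. Within sets 1 and 2 Saa2 was at 5.29 and 2.49, Hamp at 5.08 and 2, and Slc1a2 at -2.71 and -0.80. Gdap10 went the other way, at -1.14 and -2.82.

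Genes that p53 activates after DNA damage rose with DEN in WT. Of 24 measured, 13 were called higher and 11 were not called (19 higher and 1 lower adjusted over the list alone), with a median of 0.91, or 0.99 in set 1 and 0.48 in set 2 (camera adjusted p = 4.15e-20, and 0.0199 with an estimated correlation). Ccng1 rose by 2.49 (SE 0.21), the damage-bypass polymerase gene Polk by 1.29 (SE 0.15) and Phlda3 by 1.43 (SE 0.18). Nrf2 targets, which detoxify reactive compounds, also rose, with 8 of 21 higher and 13 not called (11 higher adjusted over the list alone). Their median was 0.49, 0.27 in set 1 and 1.01 in set 2 (adjusted p = 7.79e-10, and 0.00165 with an estimated correlation), with Ephx1 at 2.31 (SE 0.16), Gstp1 at 1.75 (SE 0.19) and Ugdh at 1.37 (SE 0.18). Xenobiotic metabolism genes, mostly cytochromes P450, were lower as a list at a median of -0.42, or -0.54 in set 1 and -0.28 in set 2 (adjusted p = 6.67e-05, and 0.0286 with an estimated correlation). Of 20, 3 were called lower, 1 higher and 16 not (7 lower and 1 higher adjusted over the list alone). Aldh1a1 rose by 0.94 (SE 0.18), and Cyp2c37 was at -0.75 (SE 0.19), a call that each of 3 arrays ended (adjusted p up to 0.120 without untreated WT replicate 1).

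The acute phase genes, secreted by hepatocytes in inflammation, had 8 of 20 called higher and 12 not called (10 higher and 5 lower adjusted over the list alone), with a median of 0.39, and 0.25 and 0.24 within sets 1 and 2 (adjusted p = 0.00223, and 0.268 with an estimated correlation). Saa2, Hamp and Saa1, given above, came first. Interferon-stimulated genes had 5 of 22 higher and 17 not called (6 higher and 1 lower adjusted over the list alone) at a median of 0.30, or 0.24 and 0.40 within the sets (adjusted p = 0.000509, and 0.268 with an estimated correlation). Their first members were Tap1 at 0.77 (SE 0.17), a call lost without untreated WT replicate 1 (adjusted p = 0.114), and Ddx58 at 0.49 (SE 0.13), a call that each of 3 arrays ended (adjusted p up to 0.172 without untreated WT replicate 2). Plasma protein and bile acid genes of hepatocytes had 3 of 19 lower and 16 not called (4 lower adjusted over the list alone) at a median of -0.17, or -0.24 and -0.19 (adjusted p = 0.000509, and 0.132 with an estimated correlation). Among them the bile salt pump gene Abcb11 was at -0.98 (SE 0.16) and the bile acid importer gene Slc10a1 at -0.59 (SE 0.13), the latter not called without untreated WT replicate 1 (adjusted p = 0.0617). Mitotic genes differed in direction between the array sets, with a pooled median of 0.37 (adjusted p = 5.41e-06, and 0.367 with an estimated correlation), 0.91 within set 1 and -0.60 within set 2. Of 29, only Cdk1 was called (1 adjusted over the list alone) at 0.82 (SE 0.19), and it was not called without untreated WT replicate 1 (adjusted p = 0.155). Without that array the median of the list was 0.14 (adjusted p = 0.0734).

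The same question in livers without either tumour suppressor compared 5 DEN with 3 untreated DKO arrays. Saa1 and Saa2 rose by 5.09 (SE 0.67) and 4.66 (SE 0.61), the orosomucoid genes Orm2 and Orm1 by 4.19 (SE 0.50) and 3.79 (SE 0.52), Saa3 by 3.10 (SE 0.41) and BC023105 by 2.87 (SE 0.61). The cytochrome P450 genes Cyp2b9 and Cyp2b13 were lower at -4.48 (SE 1.15) and -3.37 (SE 0.76). So were the fetal growth factor gene Igf2 at -3.07 (SE 0.49), the neutrophil granule gene Ngp at -2.99 (SE 0.44), Stfa3 at -2.70 (SE 0.81) and Abhd2 at -2.25 (SE 0.21). In total 3344 genes were called, 716 higher and 2628 lower, or 78.6% lower. With each array centred on its median the share was 52.7%, because centring moved the median of all genes by 0.107. Each of 2 arrays ended the call of Stfa3 (adjusted p up to 0.0738 without untreated DKO replicate 2). Untreated DKO arrays were all in set 1, where 4030 genes were called, and Saa1 was at 4.53, Cyp2b9 at -4.75 and Igf2 at -2.84.

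Endothelial markers fell with DEN in DKO. Of 17, 14 were called lower and 3 not (15 lower adjusted over the list alone), at a median of -0.88, or -0.74 in set 1 (camera adjusted p = 2.04e-08, and 0.128 with an estimated correlation). Stab2 was at -1.26 (SE 0.18) and Pecam1 at -0.89 (SE 0.15). Stellate cell and matrix markers had 10 of 18 lower, 1 higher and 7 not called (the same 10 and 1 adjusted over the list alone), with a median of -0.37, or -0.35 in set 1 (adjusted p = 0.000432, and 0.128 with an estimated correlation). Sparc was at -1.17 (SE 0.12) and Acta2 at -1.59 (SE 0.19). Genes of PPARalpha and ketogenesis, which burn fat in fasting, had 8 of 16 lower and 8 not called (11 lower adjusted over the list alone) at a median of -0.53, or -0.49 in set 1 (adjusted p = 5.02e-05, and 0.148 with an estimated correlation). Cpt1a was at -1.53 (SE 0.20) and Bdh1 at -1.60 (SE 0.22). Lipogenesis genes had 8 of 17 lower and 9 not called (9 lower adjusted over the list alone) at a median of -0.47, or -0.33 in set 1 (adjusted p = 0.000993, and 0.319 with an estimated correlation), with Fads2 at -1.78 (SE 0.26) and Gpam at -0.96 (SE 0.17). Gluconeogenesis and amino acid catabolism genes had 8 of 14 lower and 6 not called (8 lower and 1 higher adjusted over the list alone) at a median of -0.63, or -0.67 in set 1 (adjusted p = 0.00404, and 0.385 with an estimated correlation), with Pck1 at -1.86 (SE 0.22) and Hpd at -0.96 (SE 0.14).

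Neutrophil and myeloid precursor markers and fetal liver genes fell as well. Of 12 neutrophil markers, 5 were lower and 7 not called (7 lower adjusted over the list alone) at a median of -0.71, or -0.53 in set 1 (adjusted p = 0.00404, and 0.319 with an estimated correlation), led by Camp at -1.86 (SE 0.26) and Ngp. Of 14 fetal liver genes, 6 were lower, 1 higher and 7 not called (the same 6 and 1 adjusted over the list alone) at a median of -0.68, or -0.48 in set 1 (adjusted p = 0.0298, and 0.388 with an estimated correlation). This list was at -0.58 and not called without untreated DKO replicate 3 (adjusted p = 0.0679). Spink1 rose by 2.10 (SE 0.19) and Peg3 was at -1.66 (SE 0.26).

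The p53 targets rose in DKO too, with 8 of 24 higher, 1 lower and 15 not called (11 higher and 1 lower adjusted over the list alone) at a median of 0.31, or 0.25 in set 1 (adjusted p = 0.000105, and 0.319 with an estimated correlation). Ccng1 rose by 2.04 (SE 0.22) and Polk by 0.87 (SE 0.16). Mitotic genes had 9 of 29 higher and 20 not called (14 higher adjusted over the list alone) at a median of 0.52, or 0.73 in set 1 (adjusted p = 1.8e-06, and 0.404 with an estimated correlation), with the checkpoint kinase gene Bub1 at 1.49 (SE 0.35) and Hmmr at 1.26 (SE 0.31). DNA repair genes had 10 of 22 higher, 2 lower and 10 not called (11 higher and 2 lower adjusted over the list alone) at a median of 0.40, or 0.46 in set 1 (adjusted p = 0.000113, and 0.265 with an estimated correlation), with Fancb at 1.11 (SE 0.21) and Bard1 at 0.73 (SE 0.15). Acute phase genes went both ways. The median was -0.05 and the mean 0.86, 8 of 20 were higher, 6 lower and 6 not called (the same 8 and 6 adjusted over the list alone), and the list was not called (adjusted p = 0.201, and 0.571 with an estimated correlation), so median and test differed in sign.

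A difference between the DEN responses of DKO and WT was tested as their interaction. Hamp differed most, at -4.93 (SE 0.99). Its mean log2 signal went from 4.82 to 8.90 in WT, but was already 10.6 in untreated DKO and 10.1 after DEN. Ngp, Igf2, the fetal albumin gene Afp, Ltf and Osgin1 had interactions of -3.14 (SE 0.61), -2.81 (SE 0.68), -2.70 (SE 0.72), -2.37 (SE 0.42) and -2.34 (SE 0.44). BC023105, the lipogenic gene Thrsp and Mir15a were at 2.86 (SE 0.84), 2.63 (SE 0.82) and 2.24 (SE 0.36), and Pln, Gdpd3 and the organic anion transporter gene Slco1a1 at 2.14 (SE 0.41), 2.10 (SE 0.57) and 1.97 (SE 0.46). Like Hamp, Ngp, Igf2, Afp, Thrsp, Gdpd3 and Slco1a1 differed the opposite way in the untreated arrays used here. There were 1580 calls, 217 above 0 and 1363 below. Of these 86.3% were below 0, or 63.3% with each array centred on its median, which moved the median of all genes by 0.13. Each of 7 arrays ended the call of BC023105 (adjusted p up to 0.0897 without untreated WT replicate 2). Each of 12 ended that of Thrsp (up to 0.124 without untreated WT replicate 1). Untreated WT replicate 3 ended that of Gdpd3 (0.0764 without it). The count was 806 without untreated WT replicate 3 and 1051 without untreated DKO replicate 3. Within set 1 it was 1173, with Hamp at -5.67.

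Nrf2 targets had a lower response in DKO, with 7 of 21 below 0 and 14 not called (10 below adjusted over the list alone). The median difference was -0.40, or -0.36 in set 1 (camera adjusted p = 0.000124, and 0.0626 with an estimated correlation). Ephx1 was at -1.96 (SE 0.23) and Gstp1 at -2.30 (SE 0.28). In set 1 the mean signal of the list rose in WT, from 7.53 and 7.55 untreated to 7.92 to 7.99 after DEN. In DKO it did not rise, with 7.56 to 7.67 untreated and 7.45 to 7.57 after DEN. The p53 targets had 2 of 24 below 0 and 22 not called (3 below adjusted over the list alone) at a median of -0.39, or -0.60 in set 1 (adjusted p = 0.0219, and 0.639 with an estimated correlation). Fas was at -1.19 (SE 0.27) and Plk2 at -1.69 (SE 0.42), and each of 7 arrays ended the call of this list (adjusted p up to 0.108 without untreated WT replicate 1). Endothelial markers had 8 of 17 below 0 and 9 not called (10 below adjusted over the list alone) at a median of -0.72, or -0.44 in set 1 (adjusted p = 0.000124, and 0.358 with an estimated correlation), with Pecam1 at -0.87 (SE 0.21) and Cdh5 at -1.03 (SE 0.27). Stellate cell and matrix markers had 3 of 18 below 0 and 15 not called (4 below adjusted over the list alone) at -0.27, or -0.19 in set 1 (adjusted p = 0.0205, and 0.358 with an estimated correlation), with Sparc at -1.16 (SE 0.17) and Acta2 at -1.17 (SE 0.26). Neutrophil markers had 4 of 12 below 0 and 8 not called (7 below adjusted over the list alone) at -1.01, or -0.90 in set 1 (adjusted p = 0.00185, and 0.358 with an estimated correlation), with Ltf at -2.37 and Camp at -1.89 (SE 0.36). PPARalpha genes had 4 of 16 below 0 and 12 not called (7 below adjusted over the list alone) at -0.47, or -0.43 in set 1 (adjusted p = 0.0205, and 0.579 with an estimated correlation), with Plin2 at -1.23 (SE 0.19) and Bdh1 at -1.51 (SE 0.31). DNA repair genes lay above 0 as a list at 0.26, but only 0.09 in set 1 (adjusted p = 0.0219, and 0.639). Of 22, 1 was called above 0, 2 below and 19 not (3 above and 2 below adjusted over the list alone), with Bard1 at 0.69 (SE 0.20). Its call was ended by 7 arrays and that of the list by 3 (adjusted p up to 0.107 and 0.134 without untreated WT replicate 3).

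The effect of the DKO genotype before any damage was taken from 3 untreated DKO and 3 untreated WT arrays. Hamp was higher by 6.32 (SE 0.78) and its relative Hamp2 by 3.46 (SE 0.53). Stfa3 and Ngp were higher by 3.78 (SE 0.88) and 3.01 (SE 0.48), and the fetal genes Igf2 and Afp by 2.72 (SE 0.53) and 2.42 (SE 0.57). Gdpd3 was at -3.93 (SE 0.45), Thrsp at -2.87 (SE 0.65), Slco1a1 at -2.06 (SE 0.36), Slc1a2 at -2.05 (SE 0.38), Cyp2c50 at -2.04 (SE 0.30) and the heme synthesis gene Alas1 at -1.94 (SE 0.38). Of 177 genes called, 138 were higher and 39 lower (22.0% lower, and 34.3% with each array centred on its median). Several of these calls rested on single arrays. Untreated WT replicate 1 ended those of Stfa3 (adjusted p = 0.221 without it), Igf2 (0.122), Afp (0.204), Thrsp (0.207), Slc1a2 (0.0887) and Alas1 (0.122), and other arrays also did so, 5 arrays in all for Stfa3, Afp and Thrsp, 3 for Igf2 and Alas1 and 2 for Slc1a2. Untreated WT replicate 2 ended that of Slco1a1 (adjusted p = 0.0523). The count was 55, 59 and 311 without untreated WT replicates 1, 2 and 3, and 109, 81 and 44 without untreated DKO replicates 1, 2 and 3. Within set 1 it was 891, with Hamp at 6.99 and Gdpd3 at -3.82.

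Neutrophil and myeloid precursor markers were higher in untreated DKO as a list, with 3 of 12 higher and 9 not called (7 higher adjusted over the list alone) at a median of 1.04, or 1.17 in set 1 (camera adjusted p = 6.02e-10, and 0.025 with an estimated correlation). Camp was at 1.90 (SE 0.28) and Ngp at 3.01 (SE 0.48). Fetal liver genes had 4 of 14 higher and 10 not called (8 higher and 1 lower adjusted over the list alone) at 0.71, or 0.75 in set 1 (adjusted p = 6.84e-06, and 0.0887 with an estimated correlation). Next to Igf2, Peg3 was at 1.28 (SE 0.28), a call that each of 4 arrays ended (adjusted p up to 0.103 without untreated WT replicate 2). Among E2F and DNA replication genes, which the retinoblastoma protein represses, 2 of 34 were higher and 32 not called (9 higher adjusted over the list alone) at 0.32, or 0.38 in set 1 (adjusted p = 1.96e-08, and 0.199 with an estimated correlation). These were Mcm6 at 0.96 (SE 0.24) and Prim1 at 1.05 (SE 0.26), and each of 5 arrays ended either call (adjusted p up to 0.236 and 0.285 without untreated WT replicate 1). No mitotic gene of 29 was called (7 higher adjusted over the list alone), at a list median of 0.56, or 0.84 in set 1 (adjusted p = 9.97e-11, and 0.319 with an estimated correlation), with Cdk1 at 0.73 (SE 0.21) and Racgap1 at 0.84 (SE 0.25). None of 7 histone genes was called (2 higher adjusted over the list alone) at a median of 0.39, or 0.38 in set 1 (adjusted p = 0.00168, and 0.0314 with an estimated correlation), with H4c4 at 0.72 (SE 0.21) and H1f5 at 0.59 (SE 0.21). Xenobiotic metabolism genes had a median of -0.42, or -0.47 in set 1, with 0 of 20 called (5 lower adjusted over the list alone), the list being called lower (adjusted p = 2.22e-06, and 0.0245 with an estimated correlation). Cyp2c37 was at -0.69 (SE 0.22) and Cyp3a16 at -0.63 (SE 0.21). Plasma protein and bile acid genes had 2 of 19 lower and 17 not called (3 lower adjusted over the list alone) at -0.09, or -0.12 in set 1 (adjusted p = 0.00533, and 0.199 with an estimated correlation), a call lost without untreated WT replicate 2 (median -0.09, adjusted p = 0.0692). Baat was at -1.12 (SE 0.21) and Cyp27a1 at -0.95 (SE 0.20), calls ended by 2 and 4 arrays (adjusted p up to 0.125 and 0.180 without untreated WT replicate 1).

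**Figure D2:**
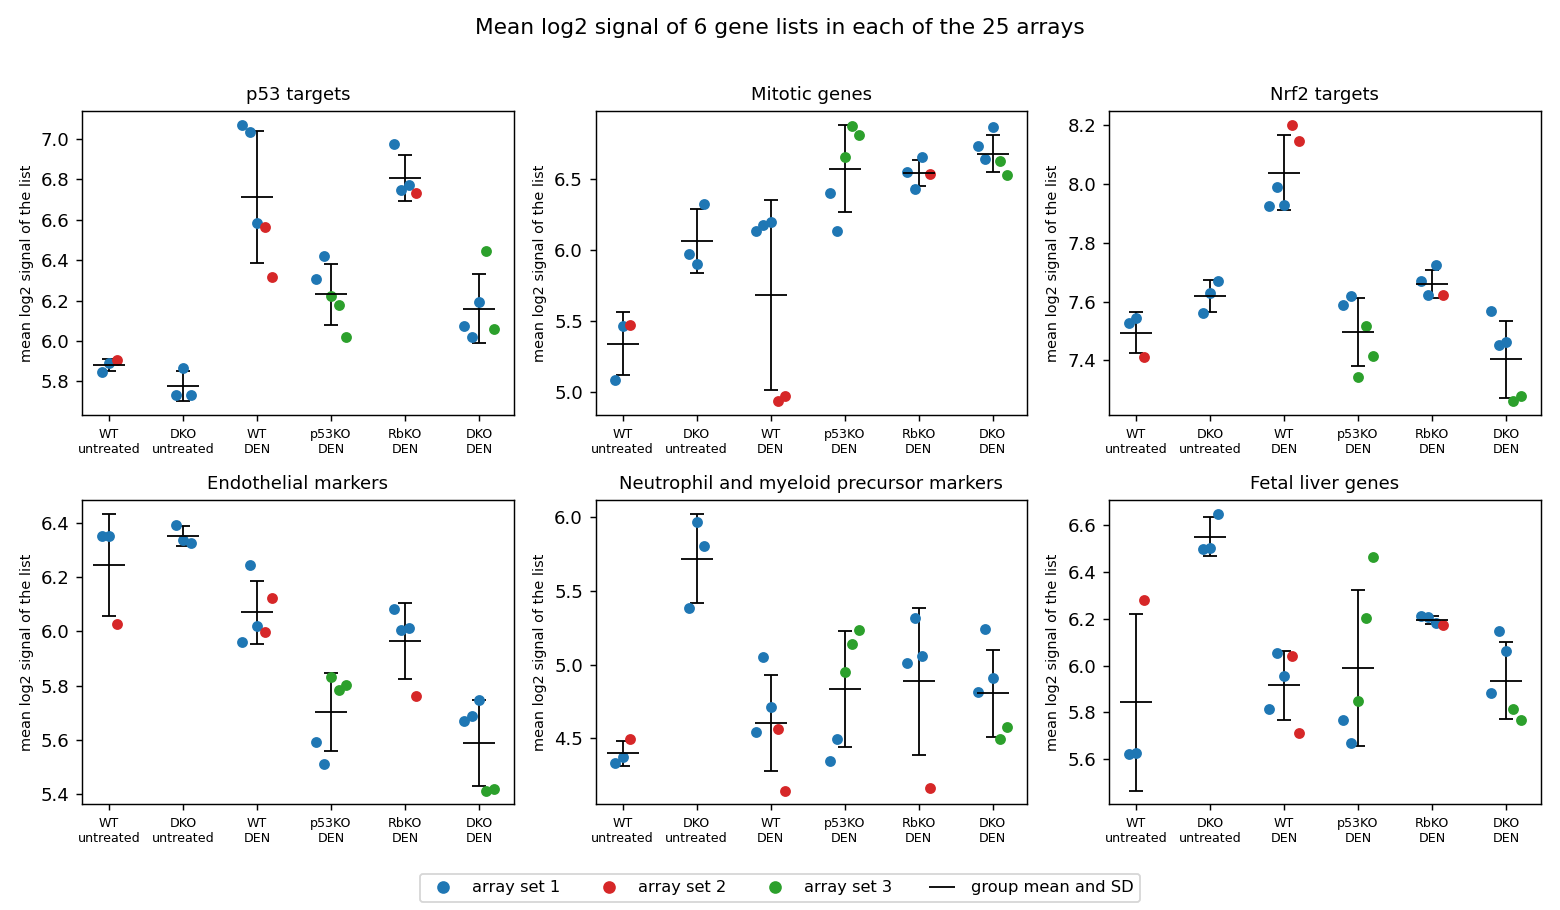
Mean log2 signal of 6 gene lists in each of the 25 arrays (vertical axis, log2), by group and coloured by array set, with bars for the group mean and SD. The 2 DEN WT arrays of set 2 lie at 4.94 and 4.98 for the mitotic genes, against 6.14 to 6.20 for the 3 of set 1, and untreated DKO arrays lie at 5.38 to 5.97 for the neutrophil markers, against 4.33 to 4.50 in untreated WT.

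What p53 contributes to the damaged liver was asked by comparing 5 DEN p53KO with 5 DEN WT arrays. Ephx1 was at -1.68 (SE 0.17), the carboxylesterase gene Ces2e at -1.56 (SE 0.15), Gria3 at -1.77 (SE 0.27), 1700007K13Rik at -1.74 (SE 0.31), Cplane1 at -1.82 (SE 0.39) and Slco1a1 at -1.63 (SE 0.34). Rsph4a was higher by 2.28 (SE 0.41), the urinary protein gene Mup3 by 1.70 (SE 0.42), Akr1c19 by 1.30 (SE 0.30), and the proliferation genes Cenpk, Pclaf and Shcbp1 by 1.34 (SE 0.33), 1.30 (SE 0.22) and 1.28 (SE 0.30). In all 284 genes were called, 113 higher and 171 lower (60.2% lower, and 47.3% with each array centred on its median). Without DEN p53KO replicate 2 the adjusted p was 0.124 for Mup3 (3 arrays ended its call), 0.125 for Cenpk (2 arrays), 0.118 for Shcbp1 (2 arrays) and 0.108 for Slco1a1. Without DEN p53KO replicate 1 it was 0.149 for Akr1c19 (3 arrays) and 0.0630 for Cplane1. The count was 35 without DEN p53KO replicate 2, 57 without DEN p53KO replicate 1 and 174 without DEN WT replicate 2. Within set 1, with 2 DEN p53KO arrays, it was 943, and Ephx1 was at -1.78. Cenpk, Pclaf and Shcbp1 were lower there than pooled, at 0.81, 0.84 and 0.77, whereas Akr1c19 was higher at 1.83.

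The p53 targets were lower in p53KO, with 5 of 24 lower and 19 not called (14 lower adjusted over the list alone) at a median of -0.58, or -0.57 in set 1 (camera adjusted p = 1.29e-10, and 0.0815 with an estimated correlation). Psrc1 was at -1.11 (SE 0.21) and Phlda3 at -0.93 (SE 0.19), both calls lost without DEN p53KO replicate 1 (adjusted p = 0.0506 and 0.0730). Nrf2 targets had 3 of 21 lower and 18 not called (7 lower adjusted over the list alone) at -0.32, or -0.31 in set 1 (adjusted p = 3.16e-06, and 0.0235 with an estimated correlation), with Ephx1 as above and Gstp1 at -1.53 (SE 0.21). Endothelial markers had 1 of 17 lower and 16 not called (11 lower adjusted over the list alone) at -0.45, or -0.56 in set 1 (adjusted p = 1.75e-07, and 0.0815 with an estimated correlation). The called gene was Gpr182 at -1.18 (SE 0.21), not called without DEN p53KO replicate 2 (adjusted p = 0.0539), and Clec4g was at -0.61 (SE 0.17). Stellate cell and matrix markers had 2 of 18 lower and 16 not called (the same 2 adjusted over the list alone) at -0.18, or -0.23 in set 1 (adjusted p = 0.00137, and 0.0815 with an estimated correlation). These 2 were Sparc at -0.54 (SE 0.12), a call that each of 4 arrays ended (adjusted p up to 0.204 without DEN p53KO replicate 2), and Acta2 at -0.77 (SE 0.19), a call that each of 5 ended (adjusted p up to 0.129 without DEN p53KO replicate 1). Mitotic genes had 1 of 29 higher and 28 not called (14 higher adjusted over the list alone) at 0.59, but 0.10 in set 1 (adjusted p = 1.42e-11, and 0.312 with an estimated correlation). Mad2l1 was at 0.91 (SE 0.24), a call that each of 8 arrays ended (adjusted p up to 0.136 without DEN p53KO replicate 1), and Bub1 at 1.28 (SE 0.35). DNA repair genes had 3 of 22 higher, 1 lower and 18 not called (11 higher and 1 lower adjusted over the list alone) at 0.39, or 0.17 in set 1 (adjusted p = 3.25e-07, and 0.0815 with an estimated correlation), with Fancb at 1.104 (SE 0.21) and Chek1 at 1.17 (SE 0.24), the latter not called without DEN p53KO replicate 1 (adjusted p = 0.0694).

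For the retinoblastoma gene the same question was put to 4 DEN RbKO and 5 DEN WT arrays. Hells, Shcbp1 and Kif20b, genes of dividing cells, were higher by 1.53 (SE 0.25), 1.53 (SE 0.26) and 1.47 (SE 0.27), Akr1c18 by 1.61 (SE 0.44), Rsph4a by 1.59 (SE 0.36) and Sult3a1 by 1.54 (SE 0.38). The aminotransferase gene Gpt was at -1.69 (SE 0.27), Gstp3 at -1.63 (SE 0.25), Gnmt at -1.44 (SE 0.22), Rdh16f2 at -1.33 (SE 0.25), and the small nucleolar RNA genes Snora44 and Snord33 at -1.44 (SE 0.34) and -1.32 (SE 0.32). The calls numbered 1811, with 834 higher and 977 lower (53.9% lower, and 34.4% with each array centred on its median). The balance turned between the sets, with 71.2% lower in set 1, 35.6% in set 2 and 74.6% without set 2. Much of this count rested on set 2. It was 279 without DEN RbKO replicate 4, the only one in set 2, 1084 without DEN WT replicate 4 and 975 without DEN WT replicate 5, and 532 within set 1. Without DEN RbKO replicate 4 the adjusted p was 0.199 for Akr1c18 (3 arrays ended its call), 0.112 for Rsph4a, 0.173 for Snora44 and 0.220 for Snord33. Hells was at 1.03 in set 1 and 2.48 in set 2, and Gpt at -1.15 and -2.69. Shcbp1 was at 0.87 and 2.81, Kif20b at 0.83 and 2.80, and Akr1c18 at 0.93 and 2.94. Sult3a1 went the other way, at 1.96 and 0.54.

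Mitotic genes rose most as a list in RbKO, with 18 of 29 higher and 11 not called (22 higher adjusted over the list alone) at a median of 0.86, or 0.39 in set 1 and 1.73 in set 2 (camera adjusted p = 3.58e-17, and 0.262 with an estimated correlation). The larger value in set 2 came from its DEN WT replicates 4 and 5, whose mean over the list was 4.94 and 4.98 against 6.14 to 6.20 in set 1, while DEN RbKO replicate 4 at 6.54 lay among the others at 6.43 to 6.66. Tpx2 was at 1.04 (SE 0.18) and Prc1 at 1.20 (SE 0.24), the latter not called without DEN RbKO replicate 4 (adjusted p = 0.0572). E2F and DNA replication genes had 13 of 34 higher and 21 not called (14 higher adjusted over the list alone) at 0.35, or 0.30 and 0.41 within the sets (adjusted p = 8.08e-12, and 0.164 with an estimated correlation). The helicase gene Mcm4 was at 0.88 (SE 0.13), Pola1 at 0.98 (SE 0.15) and Ccne2 at 1.32 (SE 0.22). DNA repair genes had 7 of 22 higher and 15 not called (13 higher adjusted over the list alone) at 0.37, or 0.29 and 0.39 (adjusted p = 2.11e-07, and 0.135 with an estimated correlation), with Chek1 at 1.14 (SE 0.21) and Brca2 at 0.88 (SE 0.19), the latter not called without DEN RbKO replicate 4 (adjusted p = 0.0883). Nrf2 targets had 5 of 21 lower and 16 not called (8 lower adjusted over the list alone) at -0.42, or -0.24 and -0.60 (adjusted p = 0.00019, and 0.0966 with an estimated correlation), with Gstp1 at -0.87 (SE 0.18) and Gstm1 at -0.65 (SE 0.14), not called without DEN RbKO replicate 4 (adjusted p = 0.0789). Acute phase genes had 5 of 20 lower and 15 not called (6 lower adjusted over the list alone) at -0.38, or -0.43 and -0.24 (adjusted p = 0.00405, and 0.447 with an estimated correlation). Hp was at -0.68 (SE 0.11) and Hpx at -0.51 (SE 0.11), and the list was not called without DEN RbKO replicate 1 (median -0.36, adjusted p = 0.0629) or DEN WT replicate 1 (adjusted p = 0.0541).

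The joint loss after DEN was read from 5 DEN DKO and 5 DEN WT arrays. Cyp2b9 and Cyp2b13 were at -4.12 (SE 1.08) and -3.38 (SE 0.71), Cplane1 at -2.15 (SE 0.36), 1700007K13Rik at -1.90 (SE 0.29), Ephx1 at -1.89 (SE 0.16) and Gdpd3 at -1.83 (SE 0.39). BC023105 was higher by 2.39 (SE 0.57), D17H6S56E-5 by 2.18 (SE 0.62), Hamp2 by 1.64 (SE 0.46), Rsph4a by 1.54 (SE 0.38), and the proliferation genes Shcbp1 and Depdc1a by 1.71 (SE 0.28) and 1.54 (SE 0.26). There were 1887 calls, 429 higher and 1458 lower, or 77.3% lower. This share was 57.4% with each array centred on its median and 66.6% after another quantile normalization. The call of Cyp2b9 was ended by each of 2 arrays (adjusted p up to 0.0640 without DEN DKO replicate 1), that of D17H6S56E-5 by 3 (0.0823 without DEN DKO replicate 3) and that of Hamp2 by 5 (0.0801 without DEN DKO replicate 2). Within set 1 the count was 1731, with Ephx1 at -1.85 and Cyp2b9 at -4.28.

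The p53 targets were lower in DKO, with 11 of 24 lower and 13 not called (19 lower adjusted over the list alone) at a median of -0.59, or -0.67 in set 1 (camera adjusted p = 1.29e-08, and 0.178 with an estimated correlation). Phlda3 was at -1.14 (SE 0.18) and the death receptor gene Tnfrsf10b at -1.11 (SE 0.21). Nrf2 targets had 10 of 21 lower and 11 not called (12 lower adjusted over the list alone) at -0.53, or -0.29 in set 1 (adjusted p = 4.42e-07, and 0.0124 with an estimated correlation), with Gstp1 at -1.48 (SE 0.19) after Ephx1. Endothelial markers had 9 of 17 lower and 8 not called (13 lower adjusted over the list alone) at -0.52, or -0.39 in set 1 (adjusted p = 6.54e-08, and 0.102 with an estimated correlation), with Tek at -1.02 (SE 0.16) and Pecam1 at -0.72 (SE 0.14). PPARalpha genes had 6 of 16 lower and 10 not called (10 lower adjusted over the list alone) at -0.47, or -0.38 in set 1 (adjusted p = 0.00414, and 0.253 with an estimated correlation), with Ehhadh at -1.11 (SE 0.20) and Plin2 at -0.69 (SE 0.13).

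Cell cycle genes went the other way in DKO after DEN. Mitotic genes had 14 of 29 higher and 15 not called (21 higher adjusted over the list alone) at 0.71, or 0.61 in set 1 (adjusted p = 2.35e-15, and 0.253 with an estimated correlation), with Top2a at 1.36 (SE 0.29) and Bub1 at 1.48 (SE 0.33). E2F and DNA replication genes had 10 of 34 higher and 24 not called (10 higher adjusted over the list alone) at 0.22, or 0.22 in set 1 (adjusted p = 4.63e-06, and 0.28 with an estimated correlation), with Pola1 at 1.02 (SE 0.17) and Rfc4 at 0.97 (SE 0.21). DNA repair genes had 9 of 22 higher, 2 lower and 11 not called (12 higher and 2 lower adjusted over the list alone) at 0.42, or 0.51 in set 1 (adjusted p = 3.01e-07, and 0.102 with an estimated correlation), with Fancb at 1.25 (SE 0.20) and Chek1 at 1.26 (SE 0.23). Interferon-stimulated genes had 5 of 22 higher and 17 not called (6 higher adjusted over the list alone) at 0.19, or 0.37 in set 1 (adjusted p = 0.000169, and 0.253 with an estimated correlation), with Ifi27l2a at 1.20 (SE 0.25) and Iigp1 at 0.87 (SE 0.19).

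What Rb1 deletion adds to p53 deletion was taken from 5 DEN DKO and 5 DEN p53KO arrays. D17H6S56E-5, BC023105 and Slco1a1 were higher in DKO by 2.69 (SE 0.55), 1.97 (SE 0.51) and 1.55 (SE 0.28), and so were the antiviral genes Trim12a, Trim30d and Ifit3, by 1.94 (SE 0.27), 1.91 (SE 0.29) and 1.41 (SE 0.29). The neighbouring genes Cyp2b9, Cyp2b13 and Cyp2b10 were at -3.70 (SE 0.96), -2.59 (SE 0.63) and -1.90 (SE 0.24), and Gdpd3, Hddc3 and 1600014C10Rik at -1.94 (SE 0.35), -1.50 (SE 0.20) and -1.45 (SE 0.26). Of 298 calls, 57 were higher and 241 lower (80.9% lower, and 68.3% with each array centred on its median). Calls were lost for BC023105 (7 arrays, adjusted p up to 0.141 without DEN p53KO replicate 1), Ifit3 (0.0578 without the same array), Cyp2b9 (8 arrays, up to 0.180 without DEN DKO replicate 5) and Cyp2b13 (7 arrays, up to 0.135 without that array). The count was 197 and 172 without DEN p53KO replicates 1 and 3 and 142 without DEN DKO replicate 5. It was 777 within set 1, of which 51.4% were lower, and 130 within set 3. Trim12a was at 1.88 in set 1 and 2.00 in set 3, and Cyp2b10 at -2.31 and -1.48.

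Interferon-stimulated genes had 2 of 22 higher in DKO than in p53KO and 20 not called (6 higher adjusted over the list alone) at a median of 0.32, or 0.62 in set 1 and 0.04 in set 3 (camera adjusted p = 6.32e-08, and 0.317 with an estimated correlation). Next to Ifit3 this was Ifi27l2a at 0.87 (SE 0.22), a call that each of 7 arrays ended (adjusted p up to 0.147 without DEN p53KO replicate 2). Xenobiotic metabolism genes had 5 of 20 lower and 15 not called (6 lower and 1 higher adjusted over the list alone) at -0.17, or -0.12 and -0.40 within the sets (adjusted p = 0.021, and 0.442 with an estimated correlation). Cyp2b10, given above, and the receptor gene Nr1i3 at -1.13 (SE 0.22) came first. The list was not called without DEN p53KO replicate 1 (median -0.24, adjusted p = 0.0867) or DEN DKO replicate 3 (adjusted p = 0.0502). PPARalpha genes had 3 of 16 lower and 13 not called (4 lower adjusted over the list alone) at -0.29 (adjusted p = 0.0124, and 0.462 with an estimated correlation), but at 0.07 in set 1 and -0.56 in set 3, and were not called without DEN DKO replicate 4 (median -0.19, adjusted p = 0.165). Plin2 was at -0.51 (SE 0.12) and Pdk4 at -0.66 (SE 0.17), calls that 4 and 9 arrays ended (adjusted p up to 0.115 and 0.116 without DEN DKO replicate 5). In 2 lists 0 genes were called and the sets went opposite ways. Macrophage markers were at 0.10, or 0.49 in set 1 and -0.15 in set 3 (0 of 16, and 1 higher adjusted over the list alone, adjusted p = 0.022, and 0.57 with an estimated correlation). Mitotic genes were at 0.13, or 0.49 and -0.18 (0 of 29, and 0 adjusted over the list alone, adjusted p = 0.0166, and 0.895). Their calls were ended by 5 and 3 arrays. Without DEN p53KO replicate 1 the macrophage median was -0.05 (adjusted p = 0.501), and without replicate 2 the mitotic 0.01 (0.634).

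What p53 deletion adds to Rb1 deletion was taken from 5 DEN DKO and 4 DEN RbKO arrays. Gipc2 was at -1.86 (SE 0.26), Gdpd3 at -1.78 (SE 0.39), Capsl at -1.72 (SE 0.27), Gria3 at -1.69 (SE 0.25), the collagen hydroxylase gene Plod2 at -1.60 (SE 0.26) and the drug efflux gene Abcb1b at -1.59 (SE 0.29). Saa3 was higher by 2.34 (SE 0.39), Hamp2 by 2.10 (SE 0.47), Orm1 by 2.01 (SE 0.50), Trim12a by 1.72 (SE 0.31), Trim30d by 1.46 (SE 0.33) and Cyp3a13 by 1.37 (SE 0.33). The 164 calls comprised 23 higher and 141 lower. Those of Orm1 and Cyp3a13 were each ended by 8 arrays (adjusted p up to 0.167 and 0.154 without DEN RbKO replicate 1), those of Hamp2 and Trim30d by 6 (0.0991 without DEN DKO replicate 2 and 0.119 without DEN DKO replicate 1) and that of Gdpd3 by 4 (0.0874 without DEN RbKO replicate 2). The count was 65 without DEN RbKO replicate 1, and 80, 95 and 106 without DEN DKO replicates 1, 2 and 3. Within set 1 it was 276, with Gipc2 at -2.22 and Saa3 at 2.21.

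The p53 targets were lower in DKO than in RbKO, with 8 of 24 lower and 16 not called (18 lower adjusted over the list alone) at a median of -0.75, or -0.71 in set 1 (camera adjusted p = 5.9e-19, and 0.0507 with an estimated correlation). Polk was at -1.20 (SE 0.15) and the apoptosome gene Apaf1 at -0.75 (SE 0.15), a call that each of 2 arrays ended (adjusted p up to 0.0811 without DEN RbKO replicate 1). Endothelial markers had 3 of 17 lower and 14 not called (8 lower adjusted over the list alone) at -0.42, or -0.37 in set 1 (adjusted p = 5.37e-08, and 0.134 with an estimated correlation), with Tek at -0.92 (SE 0.17) and Pecam1 at -0.75 (SE 0.14), not called without DEN RbKO replicate 1 (adjusted p = 0.0520). Acute phase genes had 2 of 20 higher, Saa3 and Orm1, and 18 not called (4 higher and 1 lower adjusted over the list alone) at 0.17, or 0.24 in set 1 (adjusted p = 6.84e-05, and 0.231 with an estimated correlation). Interferon-stimulated genes had 2 of 22 higher and 20 not called (4 higher adjusted over the list alone) at 0.29, or 0.45 in set 1 (adjusted p = 6.84e-05, and 0.234 with an estimated correlation). They were Ifi27l2a at 1.28 (SE 0.26) and Ifit3 at 1.36 (SE 0.33), calls that 2 and 7 arrays ended (adjusted p up to 0.0548 without DEN RbKO replicate 1 and 0.122 without DEN DKO replicate 3).

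The p53KO and RbKO livers were compared directly, with 5 and 4 DEN arrays. Gria3 was lower in p53KO at -2.55 (SE 0.27), Slco1a1 at -1.94 (SE 0.34), Abcb1b at -1.84 (SE 0.31), Cox6b2 at -1.67 (SE 0.28), Mybl1 at -1.67 (SE 0.34) and Plod2 at -1.61 (SE 0.28). Mup3 was higher by 1.86 (SE 0.42), Cyp2b10 by 1.70 (SE 0.29), Akr1c19 by 1.38 (SE 0.30), Gnmt by 1.33 (SE 0.26), Sult1c2 by 1.32 (SE 0.20) and AW112010 by 1.09 (SE 0.24). Of 92 calls, 31 were higher and 61 lower. Without DEN p53KO replicate 2 the adjusted p was 0.0532 for Cyp2b10 and for Slco1a1, 0.110 for Gnmt (3 arrays ended its call) and 0.229 for AW112010 (5 arrays). It was 0.194 for Akr1c19 (4 arrays) and 0.0537 for Cox6b2 without DEN p53KO replicate 1, and 0.146 for Mup3 (6 arrays) and 0.0638 for Mybl1 (3 arrays) without DEN RbKO replicate 1. The count was 31 and 32 without DEN p53KO replicates 1 and 2, and 35 and 60 without DEN RbKO replicates 1 and 3. Within set 1 it was 533, with Gria3 at -2.34.

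The p53 targets were lower in p53KO than in RbKO, with 5 of 24 lower and 19 not called (15 lower adjusted over the list alone) at a median of -0.58, or -0.51 in set 1 (camera adjusted p = 9.38e-19, and 0.0529 with an estimated correlation). Polk was at -1.14 (SE 0.16) and Apaf1 at -0.92 (SE 0.16), the latter not called without DEN p53KO replicate 1 (adjusted p = 0.0565). In 5 other lists 0 genes were called, although the list tests passed. E2F and DNA replication genes were at -0.22, or -0.25 in set 1 (0 of 34, and 2 lower adjusted over the list alone, list adjusted p = 9.07e-05, and 0.442 with an estimated correlation), with Pola1 at -0.72 (SE 0.18), and this list was not called without DEN p53KO replicate 2 (median -0.08, adjusted p = 0.221). Acute phase genes were at 0.30, or 0.31 in set 1 (0 of 20, and 6 higher adjusted over the list alone, list adjusted p = 2.69e-05, and 0.249 with an estimated correlation), with Orm1 at 2.07 (SE 0.53). Endothelial markers were at -0.30, or -0.52 in set 1 (0 of 17, and 5 lower adjusted over the list alone, list adjusted p = 1.19e-05, and 0.249 with an estimated correlation), with Dnase1l3 at -0.61 (SE 0.19). Mitotic genes were at -0.20, or -0.27 in set 1 (0 of 29, and 0 adjusted over the list alone, list adjusted p = 0.0151, and 0.637 with an estimated correlation). Stellate cell and matrix markers were at -0.17, or -0.16 in set 1 (0 of 18, and 0 adjusted over the list alone, list adjusted p = 0.0304, and 0.284 with an estimated correlation). For both lists 3 arrays each ended the call when left out (adjusted p up to 0.809 and 0.253 without DEN p53KO replicate 2), and the mitotic direction turned without a set term.

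Whether the DKO effect after DEN is the sum of the p53KO and RbKO effects was tested as DKO minus p53KO minus RbKO plus WT, on the log2 scale. Trim12a exceeded the sum by 2.16 (SE 0.39), Trim30d by 1.85 (SE 0.42), the ganglioside synthase gene B4galnt1 by 1.64 (SE 0.25), H2-Bl by 1.39 (SE 0.32), Phlda1 by 1.38 (SE 0.27) and the interferon-induced gene Bst2 by 1.04 (SE 0.21). Below the sum were Rsph4a at -2.32 (SE 0.49), Capsl at -1.72 (SE 0.35), Gipc2 at -1.56 (SE 0.33), Snx7 at -1.52 (SE 0.21), Mns1 at -1.46 (SE 0.30) and Gen1 at -1.32 (SE 0.26). There were 68 calls, 16 above the sum and 52 below. Only B4galnt1 and Snx7 of these 12 genes kept the call whichever array was left out. Without DEN RbKO replicate 4 the adjusted p was 0.0672 for Trim12a, 0.166 for Trim30d (12 arrays ended its call), 0.157 for H2-Bl (13), 0.156 for Phlda1 (6), 0.157 for Bst2 (8), 0.181 for Rsph4a (11), 0.158 for Capsl (6) and 0.156 for Gen1 (7). It was 0.0727 for Gipc2 (12) without DEN p53KO replicate 2 and 0.0879 for Mns1 (8) without DEN DKO replicate 5.

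This count of non-additive genes was the least stable of the 11. Without DEN WT replicates 1, 2, 4 and 5 it was 299, 229, 6 and 25, without DEN p53KO replicates 1, 2 and 3 it was 11, 41 and 26, without DEN RbKO replicates 3 and 4 it was 14 and 6, and without DEN DKO replicates 1 to 5 it was 14, 8, 104, 303 and 12. Within set 1 it was 210, with 33.3% below the sum against 76.5% in all arrays. Mitotic genes were below the sum as a list at a median of -0.72, with 0 of 29 called (11 below adjusted over the list alone, list adjusted p = 3.03e-08, and 0.459 with an estimated correlation), but at 0.07 within set 1. Prc1 was at -1.22 (SE 0.33) and Tpx2 at -0.93 (SE 0.25). E2F and DNA replication genes had 2 of 34 below and 32 not called (10 below adjusted over the list alone) at -0.25, or -0.09 in set 1 (adjusted p = 1.66e-06, and 0.459 with an estimated correlation). These were Prim1 at -1.31 (SE 0.29) and Mcm4 at -0.81 (SE 0.19), calls that 11 and 12 arrays ended (adjusted p up to 0.195 and 0.180 without DEN RbKO replicate 4). Interferon-stimulated genes were above the sum at 0.30, or 0.54 in set 1, with 0 of 22 called (1 above adjusted over the list alone, list adjusted p = 0.00333, and 0.459 with an estimated correlation), and Ifit3 was at 1.74 (SE 0.43).

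How far the genotypes share their effects was counted as genes called in the same direction. RbKO and DKO shared 831 genes, 236 higher and 595 lower, where independent calls would give 22.4 and 89.3, and 4 went opposite ways. For p53KO and DKO these were 219, with 64 higher and 155 lower against 3.04 and 15.6, and 0 opposite. For p53KO and RbKO they were 141, with 61 higher and 80 lower against 5.91 and 10.5, and 1 opposite. Because all 3 effects use the same DEN WT arrays, some likeness arises without any effect. In each of 20 simulated sets without an effect DKO had 0 calls, so its shared counts, fixed at 0, give no comparison. The simulated correlation of log2 changes across genes averaged 0.475, 0.631 and 0.395 and reached 0.707, 0.859 and 0.709. The correlations in the data, 0.690, 0.737 and 0.641, lie within that range, so they show no shared effect by themselves. The covariances, 0.0627, 0.0620 and 0.04999, exceeded the highest simulated ones, 0.0246, 0.0435 and 0.0294. In set 1 the covariances were 0.0377, 0.0357 and 0.0278. Redrawing arrays singly breaks the common shift of the set 2 DEN WT arrays, so this excess may not be a shared effect. With the DEN WT arrays split into 3 and 2, so that no control was shared, the median shared counts of 20 splits were 203.5, 46.5 and 16.5, with ranges of 0 to 552, 6 to 472 and 0 to 42, and the median correlations 0.499, 0.519 and 0.419. Genes are not independent replicates, so no p is given for these correlations.

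The DEN responses of WT and DKO, which share no array, had 214 called genes in the same direction, 66 higher and 148 lower against 14.9 and 50.3 for independent calls, and 45 in opposite directions. Their log2 changes correlated across genes at 0.255, and at 0.423 within set 1, where 876 genes were shared and 69 went opposite ways.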

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

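The tests of explanations given here were chosen only after the result was seen, except the count of genes on the chromosomes of the 2 targeted genes, of which only chromosome 14 was kept afterwards, and so was the fit with the log2 value of Xist. The search for single arrays far from their group and the test of the difference between the DEN responses were set before.

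In groups of 4 or 5 arrays, the gap between the most distant array and its nearest neighbour was divided by the range of the group, for Rb1 and the mean of each list. Of 108 such tests, 6 passed Dixon's limit, about the 5.4 that chance gives at 1 in 20. DEN WT replicate 5 had the lowest Rb1 signal (gap 0.798 of the range, 5.04 against 5.82 to 6.02 log2). DEN WT replicate 4 stood out for xenobiotic metabolism genes (0.875, 7.24 against 7.98 to 8.08) and for inflammatory cytokines and chemokines (0.878, 5.63 against 4.96 to 5.04). Among DEN RbKO arrays this held for replicate 1 with p53 targets (0.840, 6.98 against 6.73 to 6.77), replicate 2 with erythroid markers (0.950, 5.15 against 5.04 in the others) and replicate 4 with apoptosis genes (0.848, 6.37 against 6.47 to 6.49). DEN WT replicates 4 and 5 and DEN RbKO replicate 4 belong to set 2.

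The DEN response differed between DKO and WT by the interaction test for 1580 genes and for 7 lists. The differences in median response were -0.392 for p53 targets, -0.398 for Nrf2 targets, -0.465 for PPARalpha and ketogenesis genes, -1.01 for neutrophil and myeloid precursor markers, -0.715 for endothelial markers, -0.271 for stellate cell and matrix markers and 0.264 for DNA repair genes, the only list above 0. None of these 7 list differences passed with an estimated correlation (adjusted p 0.0626 for Nrf2 targets, 0.639 for p53 targets and for DNA repair genes, 0.579 for PPARalpha genes and 0.358 for the other 3). The neutrophil markers were already higher in untreated DKO, by a median of 1.04.

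Mitotic genes after DEN in WT were higher in set 1 and lower in set 2. An exchange of treated and untreated labels in set 2 is argued against by the p53 targets, which rose there by a median of 0.484 (SE 0.119 over members, 21 of 24 above 0). A shift common to all arrays of set 2 is argued against too, since the other 2 arrays of that set differed from their groups in set 1 by 0.0911 on average, within the SD of 0.163 inside groups, while the DEN WT arrays differed by -1.22. That difference of -1.22 leaves open a weaker growth or another stage of the DEN WT mice of set 2, which may differ between litters, and the labels give nothing to test it with.

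Of the 22 called genes that differed at least 2-fold between DKO and p53KO after DEN, 9 lie on chromosome 7, which holds 8.29% of the genes tested. By Fisher's exact test the odds ratio was 7.71 (p = 3.30e-05), and with neighbouring genes counted once it was 4.27 for 5 of 18 loci (p = 0.0133). Chromosome 7 was picked out of 22 after its count was seen. Among all 298 called genes it was not enriched (27 genes, Fisher's exact test, p = 0.596). Alleles linked to the targeted genes, acting on their neighbours, would change genes of chromosomes 11 and 14, so an excess on chromosome 7 cannot test them. The limit set beforehand, 2 times the expected count on both chromosomes, was not reached (1 gene against 2.64 expected). It was a poor one, as DKO and p53KO differ only in Rb1, on chromosome 14. That chromosome held 1 of the 22 genes where 0.744 would be expected (Fisher's exact test, p = 0.531), too few to tell whether linked alleles act there. Strain alleles elsewhere that DKO mice share and p53KO mice lack stay a candidate explanation, as the strain is mixed (FVB;129). Among groups that had no part in choosing the 9 genes, DEN WT replicates 3 and 4 each had the DKO-like level at 5. Those were partly different genes, with Trim12a at 4.7 and 2.5 and Cyp2b9 at 9.9 and 3.7, so equal counts need not mean shared alleles. Other DEN WT arrays had it at 0 or 1, DEN RbKO at 1 to 6, untreated WT at 0 to 3 and untreated DKO at 4 to 5. An effect of the deletions cannot be told apart from strain alleles without genotypes of these loci.

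Fetal liver, neutrophil and hepcidin genes were higher in untreated DKO. A lower share of hepatocytes as the whole cause is argued against, because the neutrophil markers exceeded the mean of 5 other cell type lists by 1.01 (SE 0.239). Those lists were at 0.08 (endothelial), 0.09 (stellate), 0.04 (lymphocyte), 0.07 (macrophage) and 0.23 (cholangiocyte). An unequal mix of the sexes as the whole cause is argued against as well, since with the log2 value of Xist in the model the medians were 1.03 for neutrophil markers (adjusted p = 9.91e-10) and 0.73 for fetal liver genes (adjusted p = 1.26e-06). A less mature liver in the DKO mice, or an effect of the deletions on maturation or on blood formation, may account for it, and these remain open, because the lowest DKO array lay only 0.222 above the highest WT array for the fetal genes, which was the set 2 array (6.28, against 5.62 and 5.63 in set 1).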

How the results depend on the processing

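Only the fits without set 2 and with Xist were chosen after seeing the data. Where a count moved, the cause was not tested. Some fits hold fewer arrays or estimate the spread from fewer groups, and counts rose in some of these and fell in others.

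No set term gave 142 genes for DEN in WT, 1256 for p53KO, 390 for RbKO, 72 for untreated DKO, 27 for DKO against p53KO, 30 for DKO against RbKO, 23 for p53KO against RbKO, 664 for the interaction and 1 for the non-additive part. The set as a random block gave 516 for p53KO, 135 for DKO against p53KO, 98 for DKO against RbKO and 55 for p53KO against RbKO. Set 1 alone gave 1747 for DEN in WT, 943 for p53KO, 532 for RbKO, 891 for untreated DKO, 777 for DKO against p53KO, 276 for DKO against RbKO, 533 for p53KO against RbKO and 210 for the non-additive part. Set 2 alone gave 204 for DEN in WT, with lone arrays assumed to vary like the others, and set 3 alone 130 for DKO against p53KO. The other comparisons lack a group in set 2 or 3 and have no value there.

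Leaving out set 2 gave 1086 for DEN in WT, 193 for RbKO, 515 for untreated DKO, 689 for DKO against p53KO, 143 for p53KO against RbKO, 881 for the interaction and 5 for the non-additive part. The covariate Xist gave 158 for p53KO, 94 for untreated DKO and 702 for the interaction. Array weights gave 1943 for DEN in WT, 676 for p53KO, 1575 for untreated DKO, 280 for DKO against RbKO, 295 for p53KO against RbKO and 16 for the non-additive part. Fitting only the groups compared gave 203 for DEN in WT, 523 for DKO, 154 for p53KO, 795 for RbKO, 1112 for untreated DKO, 168 for DKO against p53KO, 276 for p53KO against RbKO and 11 for the non-additive part. Another quantile normalization gave 117 for untreated DKO, 188 for DKO against p53KO and 102 for DKO against RbKO. For the non-additive part, a filter at the 40th percentile gave 123 and centring on the median 109. All other counts stayed within 1.5 times.

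Leaving out 1 array gave 221 to 850 genes for DEN in WT, 2396 to 3271 for DEN in DKO, 806 to 1684 for the interaction, 44 to 311 for untreated DKO, 35 to 390 for p53KO, 279 to 1970 for RbKO, 1398 to 2114 for DKO, 142 to 267 for DKO against p53KO, 65 to 200 for DKO against RbKO, 31 to 94 for p53KO against RbKO and 6 to 303 for the non-additive part.

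Rb1, called in 0 comparisons, was called in 3 with set 1 alone, 3 with array weights, 3 without set 2, 1 with centring on the median and 1 with only the groups compared. Shared DEN responses numbered 876 in set 1 and 54 without a set term, against 214. With DEN WT split, the counts shared by genotypes fell as given above. In set 1, p53KO and DKO shared 426, and RbKO and DKO 353.

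The list calls depended on the preset correlation, with 95 calls, and 8 with an estimated correlation. Directions reversed in 8 cases. Mitotic genes for DEN in WT were at -0.60 in set 2 (against 0.37) and Hnf4a in the same fit at 0.33 (against -0.76), where set 2 holds 1 untreated WT array, so these are values and not tests. The other cases were mitotic genes for the non-additive part at 0.073 in set 1 (adjusted p = 0.397, against -0.72), PPARalpha genes for DKO against p53KO at 0.066 in set 1 (adjusted p = 0.870, against -0.29), macrophage markers and mitotic genes for DKO against p53KO at -0.15 and -0.18 in set 3 (adjusted p = 0.166 and 0.0470, against 0.10 and 0.13), and mitotic genes for p53KO against RbKO with no set term (median 0.011) and with the set as a random block (median -0.075, where only the direction of the list test turned), both at adjusted p = 0.501, against -0.20. No described gene or list test reversed under another scaling, filter or leave-one-out fit. The macrophage median for DKO against p53KO did without 1 array (-0.05).

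Genes that the text or its lists name had 330 calls, a gene being counted once per comparison. Of these calls, 202 held with every single array left out, 270 under each scaling and filter, 224 without a set term and 290 in set 1. Of 68 calls of described lists, counted in the same way, these were 55, 60, 63 and 62, and 47 were called by fry. Which of array number and signal over background limits the precision more was not measured.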

Other observations

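The tests here were planned before their results were seen, except the splits within array sets, and the lists below are a selection of those not described elsewhere, out of 95 list calls in all. With DEN in DKO, circadian genes had 6 of 15 lower, 1 higher and 8 not called (7 lower and 1 higher adjusted over the list alone) at a median of -0.31, or -0.35 in set 1, with the clock repressor gene Nr1d1 at -1.80 (SE 0.24), although the list was not called (camera adjusted p = 0.079, and 0.319 with an estimated correlation). ER stress and ATF4 genes had 6 of 18 lower and 12 not called (6 lower adjusted over the list alone) at -0.20 (adjusted p = 0.15, and 0.455), with Pdia4 at -0.72 (SE 0.14) and Xbp1 at -0.75 (SE 0.16). Cholesterol synthesis genes had 4 of 16 lower and 1 higher (8 and 1 adjusted over the list alone) at -0.29 (adjusted p = 0.15, and 0.385), with Fdft1 at -0.80 (SE 0.18) and Idi1 at 0.80 (SE 0.20). Macrophage markers had 5 of 16 lower (5 adjusted over the list alone) at -0.16 (adjusted p = 0.212, and 0.572), with Lyz2 at -1.11 (SE 0.21). Lymphocyte markers had 4 of 13 lower (4 adjusted over the list alone) at -0.31 (adjusted p = 0.358, and 0.571), with Cd3d at -0.66 (SE 0.15) and the pre-B cell gene Vpreb1 at -1.69 (SE 0.43). Apoptosis genes had 5 of 17 lower and 1 higher (the same adjusted over the list alone) at -0.09 (adjusted p = 0.479, and 0.571), with Cycs at 0.74 (SE 0.16).

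Other list tests passed with few or no genes called. With DEN in WT, inflammatory cytokines and chemokines were at a median of 0.26 (0 of 17 called, adjusted p = 0.00954, and 0.268 with an estimated correlation) and erythroid markers at -0.25 (0 of 11 called, adjusted p = 0.0354, and 0.268). Interferon-stimulated genes rose with DEN in DKO too, with 6 of 22 higher and 1 lower (8 and 2 adjusted over the list alone) at 0.45 (adjusted p = 5.08e-05, and 0.265). In p53KO after DEN, ER stress genes were at -0.21 (0 of 18 called, adjusted p = 0.00419, and 0.18) and macrophage markers at -0.29 (0 of 16 called, adjusted p = 0.0208, and 0.448), the latter at 0.33 in the non-additive part (adjusted p = 0.00333, and 0.459). Cholangiocyte and progenitor markers were at 0.23 in untreated DKO and not called (adjusted p = 0.0925).

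Other splits of the same arrays were fitted to ask whether chance can be excluded as the source of each count. Splits that also exchange arrays between the sets numbered 56 for each DEN response and 100 for the comparisons named next. Only the real split was as large for DEN in WT (636 genes, highest other 428) and DEN in DKO (3344, highest other 384). The same held for p53KO (284, highest other 27), RbKO (1811, highest other 1386) and DKO (1887, highest other 412). It also held for DKO against p53KO (298, highest other 42) and DKO against RbKO (164, highest other 137). For these counts chance can be excluded. The real split was also alone for the interaction (1580, highest other 201) and the non-additive part (68, highest other 15). Those splits exchange arrays between genotypes, so they ask whether the genotypes differ at all. They cannot exclude chance as the source of a different response or of non-additivity. For RbKO the split with 1386 genes is nearly the mirror of the real one, with DEN WT replicate 3 alone left in place. For p53KO against RbKO 2 of 100 splits were as large, and the other called 214 genes against 92. That split sets all arrays of set 1 against all of sets 2 and 3, so it follows the array sets, and within set 1 the real count was 533. For untreated DKO against WT the 10 splits are too few for a share under 0.05, with 177 genes for the real split and 0 for the highest other.

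Splits that exchange arrays only within a set were fitted too. There chance can be excluded for DEN in WT (30 splits, highest other 421), RbKO (60 splits, highest other 1) and DKO against p53KO (100 splits, highest other 52). In these only the real split was as large. This held for the interaction too (100 of 200 splits, highest other 764), again without excluding chance as the source of a different response. For the non-additive part 3 of 100 splits were as large, and the highest called 224 genes against 68. Such a split mixes 4 genotypes, so effects of single deletions can enter its non-additive part, and this was not taken apart. For the other counts these splits are too few for a share under 0.05. There were 20 for DEN in DKO (highest other 143), DKO (2) and DKO against RbKO (4). Those for p53KO (highest other 155), p53KO against RbKO (1) and untreated DKO (0) numbered 10.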
